A study of Mus musculus with 12 samples.

How the data were processed

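From total RNA of cultured mouse cells of strain C57BL/6, 12 libraries were made, 3 in each of 4 groups. The growth and treatment text of the labels covers more cell types than these. It gives EGF and FGF2 at 20 ng/mL for the neurospheres, 10% serum for astrocytes and FGF2 at 20 ng/mL for astrocytes in MIM. Astrocytes came from either of 2 sources, GLAST-sorted postnatal cortex or differentiated neurospheres, and the labels do not say which was used here. Their age label is E14.5. An untreated control of the same culture batch was kept in its own medium, but replicate numbers are not said to pair samples: across genes, the deviations of libraries with the same number correlated at -0.058 to 0.097 and those of different numbers at -0.083 to 0.074. In NSC against Astrocytes the same-number values were all above 0 (0.044, 0.084 and 0.097) and the others all below it. No sequencing or library batch is given. How the tumour culture was made is not stated.

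Per the labels and the file headers, the authors computed FPKM with Cufflinks (version not given) on GRCm38, one table per library with an interval and a status for each value. The aligner, the strandedness of the libraries and any filter are not stated. Each table had 53989 lines for 53932 gene identifiers, of which 45 stood on more than 1 line, and those values were added. Of the identifiers, 99.9% were found in GENCODE release M21, and 97.5% of lines had the start and end given there. The annotation supplied biotypes, chromosomes and strands. Since strandedness is unknown, signal of overlapping genes on opposite strands was not separated.

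The files hold FPKM without counts, so depth was estimated from the intervals. These were read as spanning 2 standard deviations to each side, and the spread between replicates was larger than that error (median coefficient of variation 4.8% to 6.7% against 3.6% to 4.0% from the intervals). Intervals cover counting and assignment error only.

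Genes were tested when they reached 1 FPKM in at least 3 libraries and had the status OK in all 12. The status rule removed 43 genes, 28 of them protein coding, Gapdh included. Mvd, Slc7a5, Tubb3 and Chi3l1 of the lists had no line under those names and were not analysed here. Values were taken as log2 of FPKM plus 1 and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 libraries, 8 residual degrees of freedom and a variance prior that follows the mean. Each of 5 comparisons was adjusted over 16982 genes by Benjamini and Hochberg, and a gene is called at an adjusted p below 0.05. Tests were two-sided. Tables were read with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6 and figures drawn with matplotlib 3.10.9.

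Gene lists, 26 in number, were written from general knowledge before the data were examined, as were the comparisons, the tests and most alternatives. They held 534 genes, 21 of them on more than 1 list (such as Gfap, Egfr, Pdgfra, Aldh1l1, Mthfd2 and Sox2). Cell type lists covered neural stem and progenitor cells, astrocytes, reactive astrocytes, oligodendrocyte lineage, neurons, microglia, endothelial and mural cells, meningeal fibroblasts and ependymal cells. Of the 18 meningeal genes 6 were tested, none of them on another list. Each list was tested against all other tested genes with camera, at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 24 lists with at least 5 tested members.

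Genes named in the text followed a rule: (a) the 6 largest differences each way past 0.05, with groups that did not overlap and a mean of at least 5 FPKM in the higher group, leaving out unnamed models, pseudogenes and small RNAs, (b) from each list called, the 4 members with the smallest p in the direction of the list and up to 2 the other way, and (c) genes fixed in advance: for the treatment Gfap, S100b, Aldh1l1, Slc1a3, Sox2, Nes, Pax6, Olig2, Egfr, Pou5f1, Nanog, Klf4, Mki67, Mat2a, Ahcy, Mtr, Odc1, Tdh, Nnmt, Dnmt1, Tet1 and Ezh2, and for the others Gfap, Sox2, Nes, Olig2, Egfr, Pdgfra, Trp53, Cdkn2a and Mki67. Parts (b) and (c) went first where space was short, and some genes that the rule picks are not reported here. Aqp4, Clu, Glul, Tyms, Shmt2 and Tfcp2l1 in the treatment comparison, Ccnd1, Dusp6 and Ddx3y against NSC in Glioblastoma, and genes of the closing part were named after their values were seen. Every library of one group lay beyond every library of the other for each gene the rule named and the test called, except Sphk1. The mitochondrial transfer RNA gene mt-Tp met part (a) in MIM-Astrocytes at 79.3 ± 21.7 FPKM, but is listed at 0 in Astrocytes, so no fold is given.

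The relation of the MIM change to other differences was set against 100 simulated data sets with the spread of these libraries and no group difference. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios, quantile and common-total scaling, removal of mitochondrial genes and small RNAs, the highest line of an identifier, only the 6 libraries compared, other spread models and array weights, a replicate block, at least 2-fold in addition, and each library left out. Protein-coding genes only, rescaled to a common total, and some settings for lists that are not cell types were added after seeing the data. The fit was tested on simulated data with 50 raised genes at each size: 13, 30, 43 and 47 were found at log2 differences of 0.25, 0.5, 1 and 2, with 2 false calls.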

Results

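RNA sequencing of total RNA gave one value per gene, in FPKM (fragments scaled by transcript length and by the mapped fragments of the library), for 12 mouse libraries in 4 groups of 3. Glioblastoma was a tumour culture labelled with cerebella and E18.5. NSC were neural stem cells of E14.5 cortex grown as neurospheres with EGF and FGF2. Astrocytes were grown in medium with 10% serum, and MIM-Astrocytes, by the protocol, were moved from such medium to MIM, with a control of the same culture batch left in it. Which batch and which astrocyte source each library came from is not given, so rose and fell mean higher and lower than in Astrocytes. MIM is a serum-free medium with FGF2 and up to 6 metabolites: the amino acids threonine, methionine, cysteine and glycine, the methyl donor S-adenosylmethionine and the polyamine putrescine. The labels do not spell the name out, nor do they say which metabolites these libraries received or on which day up to day 5 they were taken. The series title concerns one-carbon metabolites and cellular identity, so the comparison of MIM-Astrocytes with Astrocytes asks what the medium did to astrocytes. The others ask how the result lies relative to stem cells and to tumour cells.

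The deposited values hold no counts. Read as counting error, their intervals imply 14000000 ± 643000 fragments in MIM-Astrocytes, 10900000 ± 681000 in Astrocytes, 11800000 ± 300000 in NSC and 11900000 ± 1080000 in Glioblastoma. Each MIM-Astrocytes library was above each Astrocytes and NSC library (exact permutation p = 0.1). The interval given with each value reached 8.7% to 10.6% of the value to either side near 10 FPKM and 27.6% to 35.3% near 1 FPKM. Between 14461 and 14919 genes per library reached 1 FPKM, and 16982 genes were tested, 12520 of them protein coding. The sum of all FPKM values, which a few abundant RNAs can move, was 580700 ± 58000 in Astrocytes, 733800 ± 65200 in MIM-Astrocytes, 764000 ± 42300 in NSC and 891400 ± 83800 in Glioblastoma (mean ± SD, n = 3). Protein-coding genes held 58.9 ± 3.81% of that sum in Astrocytes, 46.6 ± 1.95% in MIM-Astrocytes, 40.3 ± 2.95% in NSC and 43.2 ± 2.71% in Glioblastoma. The share differed between Astrocytes and each other group with p = 0.1 in a two-sided exact permutation test, the smallest that 3 against 3 libraries allow. Levels are mean FPKM ± SD over 3 libraries. Differences are of log2 of FPKM plus 1, with their SE, which pulls the difference of weakly expressed genes toward 0. The labels do not say that the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries.

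Across the tested genes, libraries of one group correlated at 0.970 to 0.971 on average. The mean correlation was 0.922 between MIM-Astrocytes and NSC, 0.854 between MIM-Astrocytes and Astrocytes, 0.797 between NSC and Astrocytes, and 0.864, 0.858 and 0.736 between Glioblastoma and NSC, MIM-Astrocytes and Astrocytes. These are correlations across genes, which are not independent replicates. The first 3 principal components held 51.2%, 23.5% and 9.9% of the variance.

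In astrocytes kept in MIM the genes of cell division rose and reactive astrocyte, contractile, matrix and interferon genes fell. Of these lists, interferon lost its call with an estimated correlation (adjusted p = 0.0583). Top2a, the topoisomerase that untangles chromosomes before mitosis (ENSMUSG00000020914.17, chromosome 11, 98992943 to 99024189, minus strand), stood at 149.7 ± 6.08 against 0.944 ± 0.0505 FPKM, log2 6.28, SE 0.07, adjusted p = 2.97e-12. Gfap, the intermediate filament protein of astrocytes (ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912, minus strand), fell (7.35 ± 0.207 against 258 ± 16.1 FPKM, log2 -4.95, SE 0.08, adjusted p = 1.19e-11). Olig2, a transcription factor of neural progenitors and the oligodendrocyte lineage (ENSMUSG00000039830.9, chromosome 16, 91225457 to 91228677, plus strand), rose (95 ± 5.87 against 3.63 ± 0.0754 FPKM, log2 4.37, SE 0.06, adjusted p = 7.41e-12). In all, 5911 of 16982 genes were higher and 4512 lower in MIM-Astrocytes, 1546 and 1432 of them by at least 2-fold. The 3 libraries of each group did not overlap for 10947 genes, 64.5%, where chance gives 10%.

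All 30 cell cycle genes tested rose (median log2 3.97, camera adjusted p = 2.94e-19, adjusted p = 0.0426 with an estimated correlation). Mki67, the antigen of cycling cells (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716361, minus strand), stood at 51.9 ± 0.887 against 0.112 ± 0.0151 FPKM, log2 5.57, SE 0.05, adjusted p = 4.51e-13. Prc1, which bundles the midzone of the mitotic spindle, stood at 91.6 ± 5.94 against 0.548 ± 0.14 FPKM, log2 5.9, SE 0.08, adjusted p = 7.41e-12. Ccna2, the cyclin of S and G2 phase, rose by a log2 difference of 3.87 and Kif11, a spindle motor, by 3.99. Pbk, a mitotic kinase, was among the genes with the largest rise of all (5.62), as were the replication-dependent histone genes Hist1h2ab and Hist1h3b (5.7 and 5.66), whose copies resemble one another so that reads can be shared between them.

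The reactive astrocyte list fell, with 2 of 28 higher and 26 lower (median log2 -2.03, camera adjusted p = 4.89e-14, adjusted p = 0.048 with an estimated correlation). C3, the central complement component (ENSMUSG00000024164.15, chromosome 17, 57203970 to 57228136, minus strand), stood at 8.79 ± 0.331 against 379 ± 17.5 FPKM, log2 -5.28, SE 0.05, adjusted p = 4.51e-13. Cp, the iron-oxidising ceruloplasmin (50.5 against 466 FPKM), fell with it. Amigo2 rose by 0.65. The rise of Sphk1 (0.32, adjusted p = 0.0468) was the only call among the named genes of this comparison whose groups overlapped, and it ended without MIM-Astrocytes replicate 2 or 3 or Astrocytes replicate 1 or 3 and after 4 of the scalings tried. Interferon response genes fell too, with 1 of 19 higher and 17 lower (median log2 -1.61, camera adjusted p = 1.35e-09, adjusted p = 0.0583 with an estimated correlation). Ifit3 stood at 4.67 ± 0.3 against 28.7 ± 2.79 FPKM, log2 -2.38, SE 0.08, adjusted p = 2.02e-09. The one that rose, Ifi27l2a (0.6, adjusted p = 0.0267), lost its call without the same libraries and after rescaling to a common total (0.114).

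Contractile and extracellular matrix genes fell, all 17 tested (median log2 -1.98, camera adjusted p = 6.88e-11, adjusted p = 0.0426 with an estimated correlation). Thbs1, a matrix glycoprotein (ENSMUSG00000040152.8, chromosome 2, 118111876 to 118127133, plus strand), stood at 1.87 ± 0.115 against 179.6 ± 4.99 FPKM, log2 -5.97, SE 0.05, adjusted p = 4.51e-13. Cyr61 and Ctgf, matricellular targets of YAP, fell (-4.08 and -3.89), and Acta2, smooth muscle actin, from 6.18 ± 0.461 to 0.169 ± 0.0215 FPKM. The meningeal fibroblast list had 0 of 6 higher and 5 lower (median log2 -1.87, camera adjusted p = 0.000417, adjusted p = 0.0938 with an estimated correlation). Ogn, a small proteoglycan, stood at 3.54 ± 0.128 against 164 ± 16.4 FPKM, log2 -5.18, SE 0.07, adjusted p = 7.14e-12. Fmod, another, stood at 0.279 against 43.1 FPKM and Islr at 17.1 against 92.6 FPKM. All 5 ependymal genes tested fell (median log2 -1.67, camera adjusted p = 0.000662, adjusted p = 0.19 with an estimated correlation), among them Foxj1, the regulator of motile cilia (11.1 ± 1.29 against 37.5 ± 4.14 FPKM). The largest fall of any named gene was that of Serpinf1, a secreted serpin (ENSMUSG00000000753.15, chromosome 11, 75409769 to 75422701, minus strand), at 6.27 ± 0.257 against 846 ± 88.6 FPKM, log2 -6.86, SE 0.1, adjusted p = 1.12e-11. Lbp, Pcp4, Cemip and the small heat shock protein gene Hspb8 fell too, with log2 differences of -5.88, -5.64, -5.39 and -5.34.

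Neural stem and progenitor genes rose on balance, with 17 of 23 higher and 5 lower (median log2 0.67, camera adjusted p = 0.00201, adjusted p = 0.286 with an estimated correlation). Hes5, a Notch target that keeps progenitors undifferentiated (ENSMUSG00000048001.7, chromosome 4, 154960923 to 154962371, plus strand), stood at 40.7 ± 4.67 against 0.684 ± 0.0998 FPKM, log2 4.63, SE 0.1, adjusted p = 9.09e-11, and Dll1, a Notch ligand, rose by 3.88. Egfr, the EGF receptor (ENSMUSG00000020122.16, chromosome 11, 16752203 to 16918158, plus strand), stood at 151 ± 13.9 against 19.9 ± 0.421 FPKM, log2 2.86, SE 0.07, adjusted p = 1.76e-10. Id4 (-2.59) and the cadherin gene Cdh2 (-1.02) fell. Sox2 rose (89.1 ± 3.87 against 61 ± 7.07 FPKM, log2 0.54, SE 0.09, adjusted p = 0.000464), as did Nes (60.6 ± 2.45 against 43.5 ± 3.99 FPKM, log2 0.47, SE 0.08, adjusted p = 0.00039). Pax6 fell (16.7 ± 1.25 against 22.1 ± 2.03 FPKM, log2 -0.39, SE 0.08, adjusted p = 0.00162). When each library was rescaled to a common total, the rises of Sox2 and Nes shrank to 0.24 and 0.17 and were no longer called. Of 12 oligodendrocyte lineage genes, 8 rose and 1 fell (median log2 0.63, camera adjusted p = 0.0202, adjusted p = 0.286 with an estimated correlation). Pdgfra, the receptor of oligodendrocyte progenitors (ENSMUSG00000029231.15, chromosome 5, 75152292 to 75198215, plus strand), stood at 2.52 ± 0.0627 against 0.375 ± 0.0288 FPKM, log2 1.35, SE 0.05, adjusted p = 3.73e-09. Gpr17 rose by 2.07, Bcas1 by 2.09 and Cspg4 by 1.28. The glioma pathway list rose, with 17 of 28 higher and 5 lower (median log2 0.43, camera adjusted p = 0.0101, adjusted p = 0.286 with an estimated correlation). Beside Egfr rose Etv5 (2.59) and Spry2 (2.35), both induced by FGF and ERK signalling, while Met (-1.97) and Cd44 (-1.26) fell.

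The astrocyte list as a whole moved both ways, with 11 of 24 higher, 7 lower and 6 not past the threshold (median log2 0.15, adjusted p = 0.742), and its mean, -0.13, differed in sign from its median and its test. Aqp4, the water channel of astrocyte endfeet, fell (35.5 ± 1.2 against 397 ± 27.7 FPKM, log2 -3.45, SE 0.06, adjusted p = 3.07e-11), and so did Clu (-3.15). In the other direction went S100b (25.4 ± 0.761 against 5.97 ± 0.573 FPKM, log2 1.92, SE 0.07, adjusted p = 2.72e-09), the glutamate transporter gene Slc1a3 (860 ± 137 against 396 ± 32.4 FPKM, log2 1.11, SE 0.12, adjusted p = 2.29e-05) and Glul, glutamine synthetase (1.76). For Aldh1l1, a folate enzyme used as an astrocyte marker, the difference of 0.09 was not past the threshold (adjusted p = 0.315), and only the fit with array weights called it (0.14, adjusted p = 0.014).

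Of the metabolic lists, DNA and histone methylation enzymes rose, with 23 of 32 higher and 3 lower (median log2 0.4, camera adjusted p = 0.00738, adjusted p = 0.0969 with an estimated correlation). Uhrf1, which recruits the maintenance methyltransferase to replicating DNA, stood at 23.4 ± 0.582 against 0.266 ± 0.151 FPKM, log2 4.27, SE 0.1, adjusted p = 1.21e-10. Dnmt1, that methyltransferase, stood at 20.6 ± 0.986 against 5.3 ± 0.511 FPKM, log2 1.78, SE 0.07, adjusted p = 5.24e-09, and Ezh2, the Polycomb methyltransferase, at 33.7 ± 3.92 against 10.4 ± 0.793 FPKM, log2 1.6, SE 0.09, adjusted p = 8.65e-08. Setd7 (-2.1) and Ezh1 (-1.21) fell. Tet1 (5.62 ± 0.267 against 4.11 ± 0.55 FPKM, log2 0.38, SE 0.09, adjusted p = 0.00387) lost its call after rescaling to a common total and without mitochondrial genes and small RNAs. The amino acid and ATF4 response list rose, with 17 of 24 higher and 3 lower (median log2 0.62, camera adjusted p = 0.0184, adjusted p = 0.645 with an estimated correlation). Slc7a11, the cystine transporter, stood at 9.62 ± 0.33 against 1.9 ± 0.124 FPKM, log2 1.87, SE 0.05, adjusted p = 3.06e-10. Asns, asparagine synthetase, stood at 37.2 ± 0.96 against 15 ± 1.29 FPKM, log2 1.26, SE 0.09, adjusted p = 8.79e-07, and Mthfd2, the mitochondrial folate enzyme, at 9.84 ± 1.05 against 2.25 ± 0.391 FPKM, log2 1.74, SE 0.14, adjusted p = 1.62e-06. Atf3 and Slc3a2 fell (-2.1 and -1).

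The one-carbon and methionine cycle list had 17 of 30 higher, 8 lower and 5 not past the threshold and was not called (median log2 0.54, adjusted p = 0.156), except after rescaling to a common total (adjusted p = 0.0381). Its members went apart: the thymidylate synthase gene Tyms rose by 3.52 and Shmt2 by 1.63, while Mtr, methionine synthase (ENSMUSG00000021311.9, chromosome 13, 12182712 to 12258113, minus strand), fell (6.86 ± 0.568 against 15.9 ± 0.103 FPKM, log2 -1.11, SE 0.06, adjusted p = 1e-07). Mat2a, which makes S-adenosylmethionine (ENSMUSG00000053907.10, chromosome 6, 72432799 to 72439558, minus strand), also fell (78.1 ± 2.19 against 97.7 ± 3.09 FPKM, log2 -0.32, SE 0.05, adjusted p = 0.000323). Ahcy, which clears its product, rose (0.6, adjusted p = 0.0228), a call that ended without MIM-Astrocytes replicate 2 (0.0831) or Astrocytes replicate 1 (0.0593) or 2 (0.0757) and, after rescaling to a common total, at 0.176. The polyamine list had 3 of 16 higher, 9 lower and 4 not past the threshold (median log2 -0.28, adjusted p = 0.156). Odc1, its entry enzyme, fell (64.1 ± 2.34 against 80.4 ± 8.21 FPKM, log2 -0.32, SE 0.08, adjusted p = 0.00735), not past the threshold with a replicate block in the 6 libraries (adjusted p = 0.0527).

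All 13 mitochondrially encoded protein genes rose (median log2 0.87, camera adjusted p = 0.00201, adjusted p = 0.279 with an estimated correlation), mt-Cytb among them (1157 ± 97.3 against 609.5 ± 31.4 FPKM, log2 0.92, SE 0.1, adjusted p = 2.66e-05), beside mt-Nd6 (1.31), mt-Nd4l (1.25) and mt-Nd2 (0.98). Their share of the FPKM sum was 2.56 ± 0.285% against 1.93 ± 0.133%. Quantile normalization ended the call of this list (adjusted p = 0.0516). Immediate early genes fell on balance, with 2 of 14 higher and 8 lower (median log2 -0.37, camera adjusted p = 0.0119, adjusted p = 0.286 with an estimated correlation). Fos stood at 2.94 ± 0.471 against 17.5 ± 1.6 FPKM, log2 -2.24, SE 0.09, adjusted p = 5.1e-09, Junb at 1.54 against 17.5 FPKM and Jun fell (-1.22), while Btg2 (1.5) and Nr4a1 (0.59) rose. The pluripotency list had 2 of 6 higher, 2 lower and 2 not past the threshold of 22 listed (median log2 0.12, adjusted p = 0.522). Klf4 stood at 0.2 ± 0.0254 against 0.141 ± 0.0543 FPKM, and Pou5f1 and Nanog, the core factors, stayed below the filter of 1 FPKM, as did Tdh and Nnmt. Tfcp2l1 of that list fell (0.29 against 28 FPKM), and the list's mean, -0.84, had, like its test, the opposite sign to its median. No call was made for cholesterol synthesis (median log2 0.34, adjusted p = 0.448), hypoxia and glycolysis (median log2 -0.03, adjusted p = 0.179) or neuronal genes (median log2 0.11, adjusted p = 0.742). The same holds for forebrain (median log2 0.37, adjusted p = 0.314), hindbrain (median log2 0.01, adjusted p = 0.732), hedgehog (median log2 0.09, adjusted p = 0.789) and sex genes (median log2 0.15, adjusted p = 0.742). Neuronal, hindbrain and hedgehog lists had means (-0.13, -0.21 and -0.09) and tests of the opposite sign to their medians.

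Of the 13 lists called here, 3 kept their call with an estimated correlation between members: cell cycle, reactive astrocyte, and contractile and extracellular matrix. The list counts were the same adjusted over the list alone, except for polyamine (4 higher, 9 lower), methylation enzymes (24, 3), cholesterol synthesis (12, 7), glioma pathway (17, 6) and sex genes (0, 0). The balance of higher and lower genes depended on the scaling: the median of all genes was 0.087 as deposited and -0.159 to 0.076 under the other scalings, with 33.9% to 55.7% of called genes higher in place of 56.7%. For the lists called here, the median kept its sign under each scaling. With only genes of mean FPKM at least 5, 8 of the 13 lists were called: methylation enzymes (adjusted p = 0.0529) and oligodendrocyte genes (0.0989) were not, and interferon, meningeal and ependymal lists had 4, 4 and 3 members left, too few for a test in any comparison, as had the forebrain list (3).

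**Figure D1:**
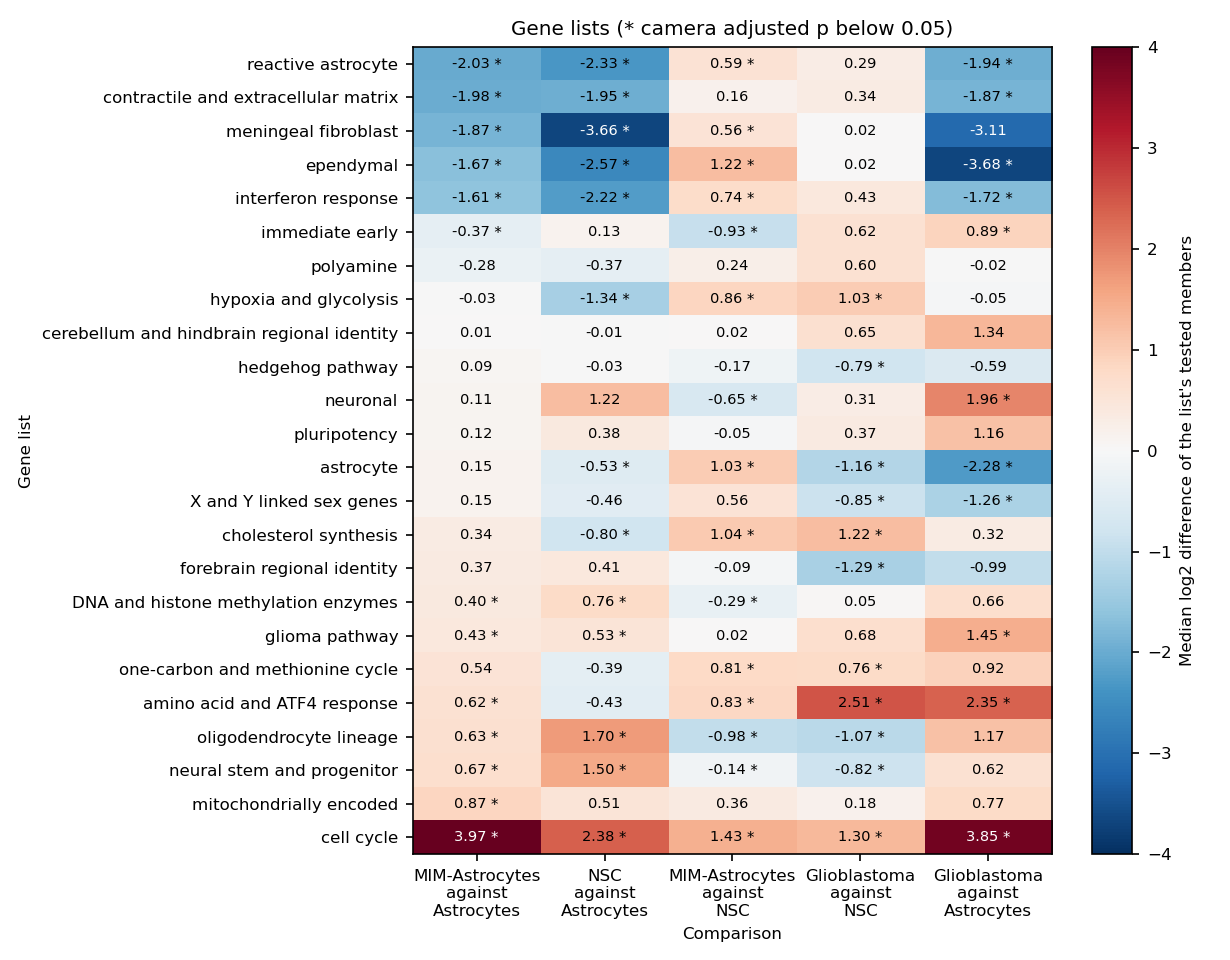
Median log2 difference of 24 gene lists (vertical) in 5 comparisons (horizontal), from lower (blue) to higher (red) in the first group named. Stars mark a camera adjusted p below 0.05. The cell cycle list is higher and interferon and reactive astrocyte lists lower in all 3 other groups than in Astrocytes. With an estimated correlation only cell cycle, reactive astrocyte and contractile and matrix in MIM-Astrocytes against Astrocytes stay below 0.05.

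Neural stem cells had higher progenitor and cell cycle genes than serum-grown astrocytes and lower reactive astrocyte, interferon, matrix, cholesterol and glycolysis genes. None of these lists kept its call with an estimated correlation (adjusted p 0.0519 to 0.455). Gfap was 0.964 ± 0.169 against 258 ± 16.1 FPKM, and C3, Serpinf1 and Clu, a secreted chaperone (ENSMUSG00000022037.15, chromosome 14, 65968483 to 65981547, plus strand), were lower (-8.53, -9.45 and -7.95). Myt1, a neural transcription factor, was 70.1 ± 1.58 against 0.028 ± 0.013 FPKM, log2 6.11, SE 0.05, adjusted p = 2.31e-13. Hes5 was 113 ± 12.8 against 0.684 ± 0.0998 FPKM, log2 6.07, SE 0.1, adjusted p = 1.25e-11. In all, 6407 genes were higher and 5680 lower in NSC, 2172 and 2217 of them by at least 2-fold, and the groups did not overlap for 12402 genes (73%, chance 10%).

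Among neural stem and progenitor genes there were 17 of 23 higher and 4 lower (median log2 1.5, camera adjusted p = 0.000413, adjusted p = 0.259 with an estimated correlation). Olig2 was 104 ± 6.87 against 3.63 ± 0.0754 FPKM, log2 4.51, SE 0.06, adjusted p = 3.57e-12, Dll1 and Dll3, Notch ligands, were higher by 4.84 and 3.92, and Cdh2 (-1.42) and Id4 (-2.14) were lower. Sox2 was 104 ± 9.06 against 61 ± 7.07 FPKM, log2 0.77, SE 0.09, adjusted p = 2.76e-05. Nes was higher by 0.43, but by 0 after rescaling to a common total (adjusted p = 0.996). The oligodendrocyte lineage list had 11 of 12 higher and 1 lower (median log2 1.7, camera adjusted p = 4.12e-05, adjusted p = 0.0903 with an estimated correlation). Pdgfra was 24.4 ± 1.44 against 0.375 ± 0.0288 FPKM, log2 4.21, SE 0.05, adjusted p = 1.82e-12. Gpr17, Bcas1 and Nkx2-2 were higher by 3.17, 3.91 and 1.62. Cell cycle genes were all higher, 30 of 30 (median log2 2.38, camera adjusted p = 7.32e-13, adjusted p = 0.0519 with an estimated correlation). Mki67 was at 20.3 ± 1.16 against 0.112 ± 0.0151 FPKM, log2 4.26, SE 0.05, adjusted p = 1.47e-12 and Top2a at 47.9 ± 4.86 against 0.944 ± 0.0505 FPKM. DNA and histone methylation enzymes had 28 of 32 higher and 2 lower (median log2 0.76, camera adjusted p = 1.6e-05, adjusted p = 0.0519 with an estimated correlation). Uhrf1 and the histone demethylase genes Kdm5b and Kdm6a were higher by 2.93, 1.35 and 1.19, and Setd7 and Ezh1 lower (-2.74 and -0.72). The glioma pathway list had 20 of 28 higher and 6 lower (median log2 0.53, camera adjusted p = 0.00907, adjusted p = 0.259 with an estimated correlation). Egfr was 170.3 ± 3.19 against 19.9 ± 0.421 FPKM, log2 3.03, SE 0.07, adjusted p = 8.5e-11. Etv1 and Etv5 were higher by 3.23 and 2.41, and Cd44 and Met were lower (-2.25 and -2.19).

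Reactive astrocyte genes were lower, with 1 of 28 higher and 27 lower (median log2 -2.33, camera adjusted p = 7.32e-13, adjusted p = 0.0519 with an estimated correlation), among them Lcn2, lipocalin (0.0195 against 45.2 FPKM). The astrocyte list had 7 of 24 higher and 14 lower (median log2 -0.53, camera adjusted p = 0.0469, adjusted p = 0.478 with an estimated correlation). Aqp4 was 10.8 ± 0.733 against 397 ± 27.7 FPKM and Acsbg1 64.2 against 302 FPKM, whereas Slc7a10 (0.98) and Fgfr3 (0.9) were higher. Its call ended after median-of-ratios scaling (0.0609), without mitochondrial genes and small RNAs (0.0518), with protein-coding genes only (0.0876) and within the 6 libraries (0.0658). Interferon response genes were lower, 19 of 19 (median log2 -2.22, camera adjusted p = 9.22e-10, adjusted p = 0.0519 with an estimated correlation). Ifit3 was at 0.607 against 28.7 FPKM. Contractile and extracellular matrix genes had 1 of 17 higher and 15 lower (median log2 -1.95, camera adjusted p = 9.61e-07, adjusted p = 0.0519 with an estimated correlation). Sparc was at 72.3 against 1277 FPKM, Thbs1 lower (-6.66) and the basement membrane collagen gene Col4a1 higher by 0.85. The meningeal list had 0 of 6 higher and 5 lower (median log2 -3.66, camera adjusted p = 0.000703, adjusted p = 0.0975 with an estimated correlation), and all 5 ependymal genes were lower (median log2 -2.57, camera adjusted p = 0.000566, adjusted p = 0.16 with an estimated correlation). Foxj1 was at 2.27 against 37.5 FPKM.

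Hypoxia and glycolysis genes were lower in NSC, with 2 of 17 higher and 15 lower (median log2 -1.34, camera adjusted p = 7.15e-05, adjusted p = 0.158 with an estimated correlation). Slc2a1, the glucose transporter, was 1.73 ± 0.0694 against 15.8 ± 1.33 FPKM, log2 -2.62, SE 0.08, adjusted p = 8.56e-10. The 2 higher were Slc16a3 (0.45) and Adm (0.6), which was not called after rescaling to a common total (0.0732). Cholesterol synthesis genes were lower, with 1 of 23 higher and 19 lower (median log2 -0.8, camera adjusted p = 0.000111, adjusted p = 0.455 with an estimated correlation). Hsd17b7 was lower (-2.19) and Acat2 higher by 0.64. The one-carbon list had 11 of 30 higher, 16 lower and 3 not past the threshold (median log2 -0.39, adjusted p = 0.33). There were, in polyamine genes, 4 of 16 higher and 9 lower (median log2 -0.37, adjusted p = 0.189) and, in the ATF4 list, 6 of 24 higher and 12 lower (median log2 -0.43, adjusted p = 0.0925). Mitochondrially encoded genes, 10 of 13 higher and 0 lower (median log2 0.51, adjusted p = 0.0502), were called without Astrocytes replicate 3 (0.0461), without a filter (0.0233) and with a replicate block (0.0465). Neuronal genes, 7 of 10 higher and 2 lower (median log2 1.22, adjusted p = 0.0925), were called after rescaling to a common total (0.00854), without mitochondrial genes and small RNAs (0.0156) and without a filter (0.00134). Immediate early (median log2 0.13, adjusted p = 0.33), pluripotency (median log2 0.38, adjusted p = 0.962) and forebrain genes (median log2 0.41, adjusted p = 0.348) were not called. Nor were hindbrain (median log2 -0.01, adjusted p = 0.851), hedgehog (median log2 -0.03, adjusted p = 0.946) and sex genes (median log2 -0.46, adjusted p = 0.407). Pluripotency, hedgehog and sex genes had means of the opposite sign to their medians (-0.58, 0.09 and 0.01), and the test had the sign of the mean for pluripotency and of the median for the others.

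Trp53 was 7.56 ± 0.7 against 5.97 ± 0.275 FPKM, log2 0.29, SE 0.08, adjusted p = 0.00892, but its difference was -0.09 after rescaling to a common total (adjusted p = 0.424). Cdkn2a, which encodes the p16 and ARF inhibitors (ENSMUSG00000044303.6, chromosome 4, 89274471 to 89294653, minus strand), was 8.57 ± 1.06 against 9.51 ± 1.04 FPKM (-0.14, adjusted p = 0.208) and was called lower after median-of-ratios scaling, rescaling to a common total and without mitochondrial genes and small RNAs (-0.19, -0.55 and -0.46). None of the 13 lists called kept its call with an estimated correlation, whose lowest adjusted p was 0.0519. Adjusted over the list alone the counts changed for polyamine (5 higher, 9 lower), cholesterol synthesis (1, 20), the ATF4 list (6, 14), immediate early (7, 4) and mitochondrially encoded genes (10, 1). The median of all genes was 0.068 as deposited and -0.284 to 0.143 under the other scalings, with 30.8% to 57.3% of called genes higher in place of 53%.

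The change in MIM ran along the difference between NSC and Astrocytes. Across 16982 genes the 2 sets of log2 differences correlated at 0.819 (Pearson, Spearman 0.758). The 100 simulations without any difference, which share the Astrocytes as baseline, gave 0.502 on average. The covariance was 0.953 against 0.04 simulated, so noise in the shared baseline held little of it. With that part subtracted, the slope on the NSC difference was 0.70. For Glioblastoma against Astrocytes the correlation was 0.698 (0.503 simulated) and the slope 0.49. In MIM-Astrocytes and NSC, 8078 genes were called the same way (4402 higher, 3676 lower) and 728 in opposite ways. Called or not, 78.3% of genes had the same sign in both, against 66.6% simulated. A real trait of Astrocytes, such as growth in serum, enters each difference, and its part in the move toward NSC was not tested. For the 4389 genes that differed by at least 2-fold between NSC and Astrocytes, MIM-Astrocytes lay at a median of 0.65 of the way from Astrocytes to NSC: 3460 lay between both groups, 219 moved away from NSC and 710 went past it.

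**Figure D2:**
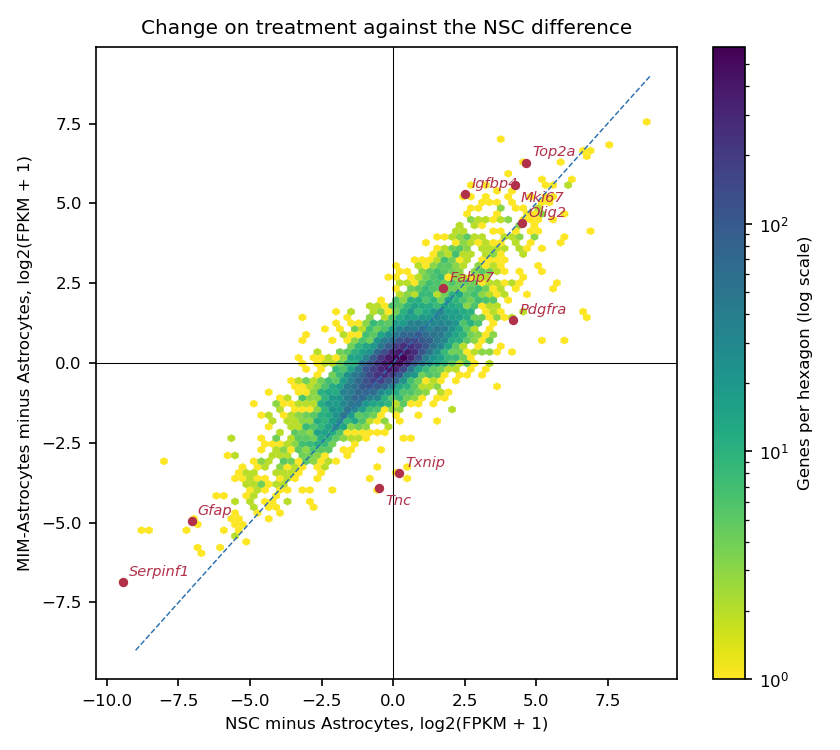
Each of 16982 genes by its log2 difference between NSC and Astrocytes (horizontal) and between MIM-Astrocytes and Astrocytes (vertical), as a density of genes with the identity line dashed. Of the 4389 genes at least 2-fold apart on the horizontal axis, 3460 lie between it and the line, Gfap and Serpinf1 among them, with Olig2 near the line, Top2a and Igfbp4 above it, and Txnip and Tnc below it.

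Set against neural stem cells, MIM-Astrocytes had more expression of cell cycle, cholesterol, glycolysis and astrocyte genes and less of oligodendrocyte, neuronal and immediate early genes. None of these lists kept its call with an estimated correlation (adjusted p 0.109 to 0.218). Clu was 94.4 ± 8.15 against 2.42 ± 0.282 FPKM, log2 4.8, SE 0.09, adjusted p = 4.82e-10. Txnip, an inhibitor of glucose uptake (ENSMUSG00000038393.14, chromosome 3, 96557957 to 96561883, plus strand), was 6.77 ± 0.812 against 96.8 ± 9.36 FPKM, log2 -3.65, SE 0.09, adjusted p = 2.08e-09. Tnc, the matrix protein tenascin C, was 1.81 ± 0.127 against 28.9 ± 1.27 FPKM, log2 -3.41, SE 0.05, adjusted p = 1.13e-10. In all, 5259 genes were higher and 4228 lower in MIM-Astrocytes, 1061 and 618 by at least 2-fold, and the groups did not overlap for 10572 genes (62.3%, chance 10%).

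Of the cell cycle genes, 29 of 30 were higher (median log2 1.43, camera adjusted p = 1.26e-13, adjusted p = 0.109 with an estimated correlation). Mki67 was at 51.9 ± 0.887 against 20.3 ± 1.16 FPKM, log2 1.32, SE 0.05, adjusted p = 1.54e-08, Rrm2, ribonucleotide reductase, at 33.4 against 7.19 FPKM and Ccna2 higher by 1.52. Mcm7 was lower (-0.25, adjusted p = 0.00591), though not after rescaling to a common total (0.446) or without mitochondrial genes and small RNAs (0.19). The astrocyte list was higher, with 18 of 24 higher and 3 lower (median log2 1.03, camera adjusted p = 0.000164, adjusted p = 0.197 with an estimated correlation). Gfap was 7.35 ± 0.207 against 0.964 ± 0.169 FPKM, log2 2.09, SE 0.08, adjusted p = 1.62e-08, and stood at 258 ± 16.1 FPKM in Astrocytes. Slc4a4, a bicarbonate transporter, was 149 against 37.4 FPKM and Aqp4 35.5 against 10.8 FPKM, and Ntsr2 (-0.99) and Slc7a10 (-0.8) were lower. Reactive astrocyte genes had 19 of 28 higher and 0 lower (median log2 0.59, camera adjusted p = 3.88e-06, adjusted p = 0.193 with an estimated correlation), C3 at 8.79 against 0.031 FPKM and Lcn2 at 4.87 against 0.0195 FPKM. Interferon response genes had 15 of 19 higher and 0 lower (median log2 0.74, camera adjusted p = 1.87e-05, adjusted p = 0.193 with an estimated correlation). Ifit3 was at 4.67 against 0.607 FPKM and Usp18 higher by 1.12. Ependymal genes had 4 of 5 higher and 0 lower (median log2 1.22, camera adjusted p = 0.0115, adjusted p = 0.278 with an estimated correlation), with Foxj1 higher by 1.88. The meningeal list had 5 of 6 higher and 1 lower (median log2 0.56, camera adjusted p = 0.00713, adjusted p = 0.193 with an estimated correlation). Islr and Ogn were higher by 3.31 and 1.93, and the 1 lower, Twist1 (-0.21, adjusted p = 0.0363), kept its call only without NSC replicate 3 among the fits that left out a library.

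Cholesterol synthesis genes were higher, with 21 of 23 higher and 0 lower (median log2 1.04, camera adjusted p = 5.28e-08, adjusted p = 0.218 with an estimated correlation). Insig1 was higher by 1.76. Hypoxia and glycolysis genes had 14 of 17 higher and 1 lower (median log2 0.86, camera adjusted p = 0.000123, adjusted p = 0.193 with an estimated correlation). Slc2a1 was at 19.1 ± 1.77 against 1.73 ± 0.0694 FPKM, log2 2.88, SE 0.08, adjusted p = 3.65e-09, Vegfa at 30.6 against 5.34 FPKM and Tpi1 higher by 1.57. Ndrg1 was lower (-0.33, adjusted p = 0.0154), not called without MIM-Astrocytes replicate 2 (0.0562) or NSC replicate 1 (0.0592). One-carbon and methionine cycle genes were higher, with 20 of 30 higher and 4 lower (median log2 0.81, camera adjusted p = 0.000164, adjusted p = 0.33 with an estimated correlation). Aldh1l2, the mitochondrial formyltetrahydrofolate dehydrogenase, was 15.3 ± 0.683 against 2.89 ± 0.426 FPKM, log2 2.07, SE 0.08, adjusted p = 1.85e-08, Ahcyl1 153 against 50.1 FPKM and Mthfd2 9.84 against 1.19 FPKM, with Mthfd2l lower (-0.68). The ATF4 list had 17 of 24 higher and 0 lower (median log2 0.83, camera adjusted p = 1.81e-05, adjusted p = 0.278 with an estimated correlation). Nupr1 was at 7.07 against 0.435 FPKM and Asns at 37.2 against 10.7 FPKM.

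Oligodendrocyte lineage genes were lower, with 0 of 12 higher and 11 lower (median log2 -0.98, camera adjusted p = 8.51e-08, adjusted p = 0.109 with an estimated correlation). Pdgfra was 2.52 ± 0.0627 against 24.4 ± 1.44 FPKM, log2 -2.85, SE 0.05, adjusted p = 3.09e-10 and Sox10 0.128 against 2.73 FPKM, and Gpr17 and Nkx2-2 were lower (-1.1 and -1.08). Neuronal genes had 1 of 10 higher and 7 lower (median log2 -0.65, camera adjusted p = 0.00118, adjusted p = 0.197 with an estimated correlation). Dcx was at 0.0893 against 3.57 FPKM and Gad1 and Elavl4 lower (-2.15 and -2.14), against Gap43 (0.59). Immediate early genes had 1 of 14 higher and 12 lower (median log2 -0.93, camera adjusted p = 2.12e-06, adjusted p = 0.139 with an estimated correlation). Egr1 was at 1.3 against 15.8 FPKM and Fos lower (-1.98), with Atf3 higher (0.32). Neural stem and progenitor genes were lower on balance, with 5 of 23 higher and 9 lower (median log2 -0.14, camera adjusted p = 0.0286, adjusted p = 0.41 with an estimated correlation). Hes5 was 40.7 ± 4.67 against 113 ± 12.8 FPKM, log2 -1.45, SE 0.1, adjusted p = 1.06e-06. Dll3 and Neurog2 were lower (-1.44 and -1.28), and Olig1 was higher by 0.5. DNA and histone methylation enzymes had 5 of 32 higher and 18 lower (median log2 -0.29, camera adjusted p = 0.00567, adjusted p = 0.147 with an estimated correlation), the demethylase genes Kdm6a, Kdm5b and Kdm4a lower (-1.3, -1.05 and -0.84), and Uhrf1 (1.35) and Dnmt1 (0.71) higher.

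Not past the threshold were Sox2 (-0.22, adjusted p = 0.0623), Nes (0.05, 0.636), Olig2 (-0.13, 0.0934) and Egfr (-0.17, 0.0512). Sox2 and Olig2 were called lower without NSC replicate 3 and Egfr without MIM-Astrocytes replicate 3, and all 3 after median-of-ratios scaling and with protein-coding genes only. Cdkn2a was lower (5.36 against 8.57 FPKM, adjusted p = 0.000373). Trp53 (-0.26, adjusted p = 0.0234) was not called without MIM-Astrocytes replicate 1 (0.075) or NSC replicate 1 (0.0623) or 2 (0.0886), nor after rescaling to a common total (0.199). Lists not called were polyamine (median log2 0.24, adjusted p = 0.628), pluripotency (median log2 -0.05, adjusted p = 0.582), contractile and matrix (median log2 0.16, adjusted p = 0.863) and glioma pathway (median log2 0.02, adjusted p = 0.839, test lower). Regional lists, forebrain (median log2 -0.09, adjusted p = 0.69) and hindbrain (median log2 0.02, adjusted p = 0.69, mean -0.08 and test lower), were not called either. The remaining lists without a call were hedgehog (median log2 -0.17, adjusted p = 0.0896), mitochondrially encoded (median log2 0.36, adjusted p = 0.0901) and sex genes (median log2 0.56, adjusted p = 0.296). None of the 15 lists called kept its call with an estimated correlation, and the meningeal list was not called without a filter on low values (0.21), where the hedgehog (0.0405) and mitochondrially encoded lists (0.0209, and 0.0432 after quantile normalization) were called. Adjusted over the list alone, 1 more gene was lower in the neural stem, pluripotency, methylation, neuronal, hypoxia and glioma lists and 1 more higher in the polyamine, cholesterol, ATF4 and interferon lists. The median of all genes was 0.022 as deposited and -0.049 to 0.124 under the other scalings, with 46.1% to 67.6% of called genes higher in place of 55.4%.

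**Figure D3:**
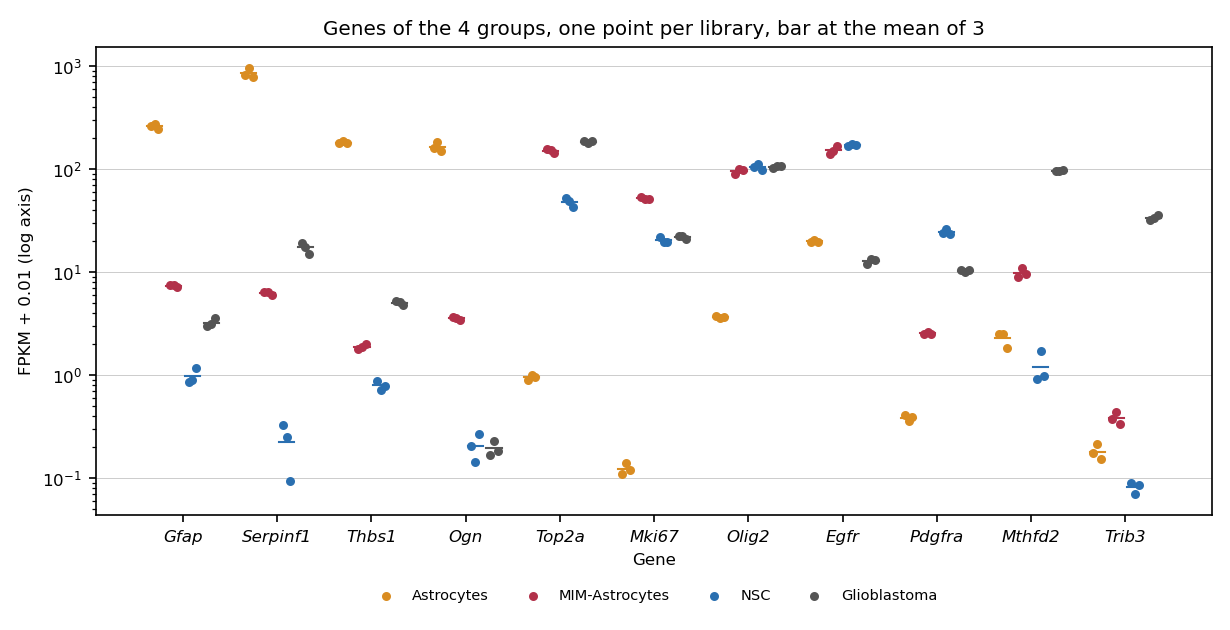
FPKM plus 0.01 on a log axis for 11 genes, with a point for each library of the 4 groups and a bar at the group mean. Gfap, Serpinf1, Thbs1 and Ogn are highest in the 3 Astrocytes libraries, and Top2a and Mki67 are lowest there.

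Glioblastoma cultures had more expression of amino acid response and glycolysis genes than NSC and less of astrocyte genes and of Egfr, though none of these lists kept its call with an estimated correlation (adjusted p = 0.219). Cdkn2a was 109 ± 4.35 against 8.57 ± 1.06 FPKM, log2 3.53, SE 0.09, adjusted p = 3.8e-10. Apoe, the lipid carrier of glia (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188, minus strand), was 16.3 ± 0.793 against 3685 ± 345 FPKM, log2 -7.73, SE 0.12, adjusted p = 1.71e-11. Egfr was 12.8 ± 0.745 against 170.3 ± 3.19 FPKM, log2 -3.64, SE 0.07, adjusted p = 4.25e-11. Ccnd1, the G1 cyclin, was 346 ± 8.53 against 9.96 ± 1.28 FPKM, log2 4.99, SE 0.08, adjusted p = 2.27e-11. In all, 7611 genes were higher and 4265 lower in Glioblastoma, 2354 and 1312 by at least 2-fold, and the groups did not overlap for 12728 genes (74.9%, chance 10%).

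All 24 genes of the amino acid and ATF4 response list were higher (median log2 2.51, camera adjusted p = 1.45e-09, adjusted p = 0.219 with an estimated correlation). Trib3, a stress-induced pseudokinase, was 33.6 ± 1.64 against 0.0711 ± 0.00953 FPKM, log2 5.01, SE 0.05, adjusted p = 1.76e-12. Chac1, which degrades glutathione, was 41.1 ± 0.633 against 0.164 ± 0.0447 FPKM, log2 5.18, SE 0.05, adjusted p = 1.62e-12. Nupr1 was 87.8 against 0.435 FPKM. One-carbon and methionine cycle genes had 22 of 30 higher and 3 lower (median log2 0.76, camera adjusted p = 0.0059, adjusted p = 0.551 with an estimated correlation). Mthfd2, which is on both lists, was 95.5 ± 1.52 against 1.19 ± 0.452 FPKM, log2 5.48, SE 0.14, adjusted p = 2.96e-10. Shmt2 was 198 ± 3.51 against 16.3 ± 1.2 FPKM, log2 3.53, SE 0.08, adjusted p = 1.82e-10, and Aldh1l2 and the folate carrier gene Slc19a1 were higher by 4.57 and 2.05. Aldh1l1 (2.24 ± 0.239 against 97.2 ± 7.02 FPKM, log2 -4.92, SE 0.08, adjusted p = 1.59e-11) and Ahcyl1 (-0.48) were lower. With only genes of mean FPKM at least 5, this list was not called (0.0613). Hypoxia and glycolysis genes had 16 of 17 higher and 0 lower (median log2 1.03, camera adjusted p = 0.000229, adjusted p = 0.219 with an estimated correlation). Vegfa was at 179.6 ± 0.618 against 5.34 ± 0.764 FPKM, log2 4.84, SE 0.09, adjusted p = 5.02e-11 and Hk2, Ndrg1 and Tpi1 higher by 3.76, 2.25 and 2.18. Cholesterol synthesis genes had 22 of 23 higher and 0 lower (median log2 1.22, camera adjusted p = 3.09e-05, adjusted p = 0.397 with an estimated correlation), with Fdps and Sqle higher by 2.24 and 2.18. Cell cycle genes had 28 of 30 higher and 1 lower (median log2 1.3, camera adjusted p = 7.35e-07, adjusted p = 0.219 with an estimated correlation), the replication genes Mcm3, Cdc6 and Mcm5 higher by 3.09, 2.52 and 2.39 and the mitotic gene Cdc20 lower (-0.54). Mki67 was 21.8 ± 0.69 against 20.3 ± 1.16 FPKM (0.1, adjusted p = 0.0849), lower after quantile normalization and with protein-coding genes only (-0.21 in each) and called higher without NSC replicate 1 (0.15).

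The astrocyte list was lower, with 5 of 24 higher and 17 lower (median log2 -1.16, camera adjusted p = 3.09e-05, adjusted p = 0.219 with an estimated correlation). Slc4a4 (-3.84) and Aqp4 (-3.38) were lower, whereas Clu (28.2 against 2.42 FPKM) and Gfap (3.2 ± 0.31 against 0.964 ± 0.169 FPKM, log2 1.1, SE 0.08, adjusted p = 4.7e-07) were higher. Neural stem and progenitor genes were lower, with 4 of 23 higher and 17 lower (median log2 -0.82, camera adjusted p = 3.09e-05, adjusted p = 0.219 with an estimated correlation), among them Id4 (-3.21) and Neurog2 (-1.63), while Hes1 (54 against 23.8 FPKM) was higher. The oligodendrocyte list had 4 of 12 higher and 8 lower (median log2 -1.07, camera adjusted p = 0.0316, adjusted p = 0.377 with an estimated correlation), a call that ended under each scaling except rescaling to a common total, within the 6 libraries, without a filter and at a mean FPKM of at least 5 (0.0516 to 0.0999): Gpr17 and Pdgfra were lower (-2.64 and -1.17) and Nkx2-2 was 28 against 2.17 FPKM. Forebrain regional genes had 1 of 10 higher and 8 lower (median log2 -1.29, camera adjusted p = 0.00166, adjusted p = 0.219 with an estimated correlation). Lhx2 was 5.67 against 25.8 FPKM and Lmo3 3.25 against 20 FPKM, against Dlx1, higher by 1.41. Hindbrain genes had 5 of 9 higher and 4 lower (median log2 0.65, adjusted p = 0.863, mean -0.01). Hedgehog pathway genes were lower on balance, with 3 of 12 higher and 8 lower (median log2 -0.79, camera adjusted p = 0.0218, adjusted p = 0.229 with an estimated correlation) and a call that ended with protein-coding genes only (0.0819). Ptch1, the receptor, was 12.7 ± 1.39 against 41.9 ± 0.571 FPKM, log2 -1.66, SE 0.09, adjusted p = 4.92e-08, Boc and Cdon, its co-receptors, were lower (-1.82 and -1.31), and Ccnd2 (2.77) and Mycn (1.22) were higher.

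All 5 sex-linked genes were lower (median log2 -0.85, camera adjusted p = 0.00233, adjusted p = 0.216 with an estimated correlation). Xist, the RNA that silences an X chromosome in female cells (ENSMUSG00000086503.3, chromosome X, 103460375 to 103483217, minus strand), was 0.14 ± 0.0528 against 103 ± 11 FPKM, log2 -6.51, SE 0.13, adjusted p = 5.02e-11, and the Y genes Kdm5d, Uty, Eif2s3y and Ddx3y were lower (-0.85, -0.9, -0.59 and -0.24). Rab3b and Moxd1 had the largest rises of named genes (6.42 and 6.38). Those of Rpl21 (5.47), Cox6a2 (5.89) and the fall of Mt2 (-5.77) concern families with similar copies whose reads can be shared. Trp53 was 16.8 ± 0.332 against 7.56 ± 0.7 FPKM, log2 1.06, SE 0.08, adjusted p = 1.14e-06. Sox2 was 136 ± 6.48 against 104 ± 9.06 FPKM, log2 0.39, SE 0.09, adjusted p = 0.00341, a call that ended after quantile normalization (0.582), rescaling to a common total (0.0703) and with protein-coding genes only (0.22). Nes was lower (-0.32). Olig2 was 105 ± 3.25 against 104 ± 6.87 FPKM (adjusted p = 0.836), but lower after median-of-ratios scaling (-0.14), quantile normalization (-0.3) and with protein-coding genes only (-0.3).

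Lists not called were reactive astrocyte (median log2 0.29, adjusted p = 0.105), polyamine (median log2 0.6, adjusted p = 0.0824), pluripotency (median log2 0.37, adjusted p = 0.184), and methylation enzymes (median log2 0.05, adjusted p = 0.264, test lower). Nor were contractile and matrix (median log2 0.34, adjusted p = 0.184), neuronal (median log2 0.31, adjusted p = 0.92), meningeal (median log2 0.02, adjusted p = 0.754), or ependymal genes (median log2 0.02, adjusted p = 0.264, mean -0.38). The others were interferon (median log2 0.43, adjusted p = 0.184), immediate early (median log2 0.62, adjusted p = 0.255), glioma pathway (median log2 0.68, adjusted p = 0.0553) and mitochondrially encoded genes (median log2 0.18, adjusted p = 0.863, test lower). The glioma pathway was called without Glioblastoma replicate 3 (0.0443) or NSC replicate 3 (0.036), after rescaling to a common total (0.0462), at a pseudocount of 0.1 (0.0486) and without a filter (0.00106). Dusp6, a target of ERK signalling on it, was higher by 3.24. The reactive astrocyte list was called after quantile normalization (0.00641), rescaling to a common total (0.0463), without mitochondrial genes and small RNAs (0.0343), with protein-coding genes only (0.0481), without a filter (0.00337) and at a pseudocount of 0.1 (0.0453). The interferon list was called after quantile normalization (0.0158) and without a filter (0.0262), and methylation enzymes after quantile normalization (0.0456). Without a filter the polyamine (0.00591) and contractile and matrix lists (0.0092) were called too, and the forebrain list was not (0.113). None of the 11 lists called kept its call with an estimated correlation. Adjusted over the list alone the neural stem list had 5 higher and 17 lower and the mitochondrially encoded list 5 and 1. The median of all genes was 0.191 as deposited and 0.001 to 0.114 under the other scalings, with 50.3% to 59.4% of called genes higher in place of 64.1%. In all, 40 calls changed direction after quantile normalization and 27 with protein-coding genes only.

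Against Astrocytes, Glioblastoma had higher cell cycle, amino acid response, immediate early and glioma pathway genes and lower astrocyte, reactive astrocyte and interferon genes. None of these lists kept its call with an estimated correlation (adjusted p 0.113 to 0.212). Aqp4 was 0.125 ± 0.0285 against 397 ± 27.7 FPKM, log2 -8.47, SE 0.06, adjusted p = 7.95e-14 and Apoe 16.3 ± 0.793 against 5375 ± 618 FPKM, log2 -8.27, SE 0.12, adjusted p = 3.52e-12. Top2a was 183 ± 5.6 against 0.944 ± 0.0505 FPKM, log2 6.56, SE 0.07, adjusted p = 7.33e-13. Dusp6 was 367 ± 3.96 against 9.52 ± 0.63 FPKM, log2 5.13, SE 0.07, adjusted p = 2.83e-12. In all, 7983 genes were higher and 5311 lower in Glioblastoma, 3705 and 2463 by at least 2-fold, and the groups did not overlap for 13566 genes (79.9%, chance 10%).

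All 30 cell cycle genes were higher (median log2 3.85, camera adjusted p = 2.18e-11, adjusted p = 0.113 with an estimated correlation), Mki67 by 4.36 and Kif11 by 4.04. The ATF4 list had 23 of 24 higher and 0 lower (median log2 2.35, camera adjusted p = 2.87e-07, adjusted p = 0.212 with an estimated correlation). Asns was at 320.2 ± 15.2 against 15 ± 1.29 FPKM, log2 4.33, SE 0.09, adjusted p = 3.38e-11 and Trib3 and Chac1 higher by 4.89 and 4.66. Immediate early genes had 12 of 14 higher and 0 lower (median log2 0.89, camera adjusted p = 0.00333, adjusted p = 0.212 with an estimated correlation). Ier3 was at 53 against 5.98 FPKM, Egr1 at 7.9 against 1.92 FPKM and Ier2 higher by 2.1. Glioma pathway genes had 22 of 28 higher and 6 lower (median log2 1.45, camera adjusted p = 0.0036, adjusted p = 0.212 with an estimated correlation). Ccnd1 was 346 ± 8.53 against 6.72 ± 0.576 FPKM, log2 5.49, SE 0.08, adjusted p = 4.07e-12. Spry4 and Pdgfra were higher by 3.86 and 3.04, and Cd44 and Met were lower (-2.14 and -1.6). Neuronal genes had 9 of 10 higher and 1 lower (median log2 1.96, camera adjusted p = 0.0124, adjusted p = 0.281 with an estimated correlation), Elavl4, an RNA-binding protein gene of neurons, at 13.5 against 0.157 FPKM and Gap43 at 42.8 against 7.81 FPKM, with Syp lower (-1.44).

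Astrocyte genes were lower, with 3 of 24 higher and 20 lower (median log2 -2.28, camera adjusted p = 1.3e-07, adjusted p = 0.114 with an estimated correlation). Gfap was 3.2 ± 0.31 against 258 ± 16.1 FPKM, log2 -5.95, SE 0.08, adjusted p = 1.69e-12 and Slc4a4 was lower (-4.26), whereas Cbs, a transsulfuration enzyme, was 116 ± 4.84 against 18.1 ± 4.57 FPKM, log2 2.65, SE 0.21, adjusted p = 7.54e-07. Reactive astrocyte genes had 4 of 28 higher and 23 lower (median log2 -1.94, camera adjusted p = 1.61e-08, adjusted p = 0.114 with an estimated correlation), with C3, Cp and Lcn2 lower (-8.52, -7.1 and -5.37) and Timp1 (29.4 against 2.25 FPKM) and Amigo2 (1.41) higher. Interferon genes had 0 of 19 higher and 18 lower (median log2 -1.72, camera adjusted p = 1.61e-08, adjusted p = 0.113 with an estimated correlation). Ifit3 was at 0.172 against 28.7 FPKM. Contractile and matrix genes had 4 of 17 higher and 12 lower (median log2 -1.87, camera adjusted p = 0.000218, adjusted p = 0.114 with an estimated correlation), Thbs1 and Cyr61 lower (-4.91 and -4.49) and Col4a1 higher by 1.24. All 5 ependymal genes were lower (median log2 -3.68, camera adjusted p = 0.000684, adjusted p = 0.198 with an estimated correlation), and all 5 sex-linked genes (median log2 -1.26, camera adjusted p = 0.00276, adjusted p = 0.113 with an estimated correlation), among them Xist (-4.35) and Ddx3y (-1.26). The largest falls were those of Mt2, a metallothionein (-9.21), and A2m, a protease inhibitor (-9), and the largest rises those of Moxd1 (7.08) and the corepressor gene Tle6 (6.67).

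Sox2 was 136 ± 6.48 against 61 ± 7.07 FPKM, log2 1.15, SE 0.09, adjusted p = 7.72e-07. Cdkn2a was 109 ± 4.35 against 9.51 ± 1.04 FPKM, log2 3.39, SE 0.09, adjusted p = 1.73e-10. Egfr was 12.8 ± 0.745 against 19.9 ± 0.421 FPKM, log2 -0.6, SE 0.07, adjusted p = 1.29e-05, and Olig2 and Trp53 were higher by 4.52 and 1.35. Nes was 46.6 ± 1.01 against 43.5 ± 3.99 FPKM (adjusted p = 0.247), but lower after quantile normalization (-0.22), rescaling to a common total (-0.43) and without mitochondrial genes and small RNAs (-0.4). Lists not called were neural stem and progenitor (median log2 0.62, adjusted p = 0.581), pluripotency (median log2 1.16, adjusted p = 0.691), one-carbon (median log2 0.92, adjusted p = 0.262), polyamine (median log2 -0.02, adjusted p = 0.683, mean 0.14) and methylation enzymes (median log2 0.66, adjusted p = 0.058). Cholesterol synthesis (median log2 0.32, adjusted p = 0.369), oligodendrocyte (median log2 1.17, adjusted p = 0.088), meningeal (median log2 -3.11, adjusted p = 0.0607) and hypoxia genes (median log2 -0.05, adjusted p = 0.522, mean 0.17) were not called. Nor were forebrain (median log2 -0.99, adjusted p = 0.155), hindbrain (median log2 1.34, adjusted p = 0.993, mean -0.14), hedgehog (median log2 -0.59, adjusted p = 0.233) and mitochondrially encoded genes (median log2 0.77, adjusted p = 0.156). Methylation enzymes were called without Glioblastoma replicate 3 (0.0483) or Astrocytes replicate 3 (0.0349) and without a filter (0.00143), and the oligodendrocyte list under 4 scalings (0.00726 to 0.0481) and without a filter (0.0109).

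None of the 11 lists called kept its call with an estimated correlation. Adjusted over the list alone, 1 more gene was lower in the one-carbon and cholesterol lists. The median of all genes was 0.227 as deposited and -0.212 to 0.107 under the other scalings, and the share of called genes that were higher was 60% and 39.7% to 54.4%. Calls that changed direction numbered 156 after rescaling to a common total, 309 without mitochondrial genes and small RNAs and 71 after quantile normalization. Microglia and endothelial or mural genes had 2 tested members each, too few for a test: 18 of 20 microglia genes and 13 of 16 endothelial or mural genes stayed below 1 FPKM in each library.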

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

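The tests of explanations below were chosen after the results were seen, the splits of the samples before.

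RNA of 2 genes had a usable value in a single library: Rn7sk stood at 87080 FPKM and Malat1 at 5344 FPKM in MIM-Astrocytes replicate 1, while the other 11 libraries carried the Cufflinks status for too many fragments. Both were outside the comparisons. That library also lay further from replicates 2 and 3 than they from each other: the median squared difference was 2.94 and 2.54 times the variance of the intervals, against 1.17, and 0.81 to 2.32 within the other groups. Whether its Cufflinks settings differed is unstated and open. In all, 5 genes had the status OK in 1 library, the other 3 (RP24-458F14.4, RP24-458F14.3 and Gm27694) at values near 0.

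The cell cycle list rose in MIM-Astrocytes with all 30 genes. Scaling between libraries is argued against: the median log2 difference of the list was at least 3.91 under each scaling, where the median of all genes was -0.159 to 0.087. Neural stem cells of the measured profile mixed into the treated cultures are argued against as the whole cause, because a mixture lies between its parts and 29 of the 30 genes were above all NSC and Astrocytes libraries in each treated library, against 14% of all genes. Serum-free base medium with FGF2 rather than the metabolites could also account for the rise, and 0 libraries of astrocytes in that medium alone were analysed, so the design cannot separate it from the metabolites. A different astrocyte source for the 2 groups would go against the protocol, which describes controls of the same batch, and was not tested for this or the next pattern. Entry into division under MIM stays a hypothesis.

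Contractile, matrix and meningeal genes were lower in MIM-Astrocytes, though the meningeal list lost its call with an estimated correlation (adjusted p = 0.0938), and scaling between libraries is argued against, as the median log2 differences of the contractile and matrix list and of the meningeal list were at or below -1.87 under each scaling. Meningeal fibroblasts in the untreated cultures are argued against: Dcn and Lum, abundant in such cells, reached at most 0.098 FPKM in an untreated library, where Ogn was at 163.8, Islr at 92.6 and Fmod at 43.1 FPKM. Col1a2, Col3a1, Mgp and Igf2 stayed at or below 0.104 FPKM there and Col1a1 at 2.69 ± 0.655, and a GLAST sort, which would remove fibroblasts, applies to 1 of the 2 described sources. Removal of serum rather than the metabolites may explain the fall, since serum induces such genes, and 0 libraries of astrocytes in the base medium alone were analysed.

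Xist was higher in NSC (103 ± 11 FPKM) than in Astrocytes (22.4 ± 3.44) and MIM-Astrocytes (29.4 ± 3.73), with a log2 difference of 2.16 against Astrocytes. Scaling between libraries is argued against, since the difference was at least 1.75 under each scaling. A larger share of female cells in the NSC libraries could explain it: 3 of 4 Y genes were lower in NSC, Ddx3y (-1.02), Eif2s3y (-0.56) and Uty (-0.46). Kdm5d, at -0.05 (adjusted p = 0.566), did not go with them. Against MIM-Astrocytes all 4 were lower in NSC: MIM-Astrocytes were higher in Ddx3y (0.96), Uty (0.62), Eif2s3y (0.56) and Kdm5d (0.21, adjusted p = 0.0292). The Y genes did not differ by one factor, so this stays open, and the sex of the animals is not in the labels.

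Each comparison has 10 splits of its 6 libraries into 3 against 3, so no share under 0.1 can be had, and the real split alone, 1 of 10, gave its count. The real splits called 10423 genes (MIM-Astrocytes against Astrocytes), 12087 (NSC against Astrocytes), 9487 (MIM-Astrocytes against NSC), 11876 (Glioblastoma against NSC) and 13294 (Glioblastoma against Astrocytes), and the highest of the other splits 3, 4, 4, 4 and 2.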

How the results depend on the processing

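The protein-coding setting was chosen after seeing the data. Of named-gene results, 5962 kept direction and side of the threshold, 42 lost the call, 18 gained one and 9 changed sign. Of list results, the estimated correlation aside, 1465 kept, 20 lost and 30 gained it. Without 1 library, 2263 gene and 715 list results kept, 25 and 0 lost and 4 and 5 gained it. With 1 library out, genes higher and lower numbered 5360 to 5957 and 4183 to 4527 (MIM-Astrocytes against Astrocytes), 5945 to 6359 and 5306 to 5730 (NSC against Astrocytes), 4697 to 5186 and 3723 to 4158 (MIM-Astrocytes against NSC), 7028 to 7407 and 4024 to 4186 (Glioblastoma against NSC), and 7610 to 7951 and 5058 to 5273 (Glioblastoma against Astrocytes). Lists called were 13, 13 to 14, 15, 11 to 12 and 11 to 12 in that order, genes shared by MIM-Astrocytes and NSC 7460 to 8018, and the correlations with the NSC and Glioblastoma differences 0.809 to 0.823 and 0.688 to 0.703.

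No cause was tested below except where fewer genes or a stricter threshold make the change. Asking for at least 2-fold left, in the same order, 1546, 2172, 1061, 2354 and 3705 genes higher and 1432, 2217, 618, 1312 and 2463 lower. An estimated correlation left 3, 0, 0, 0 and 0 lists. With a mean FPKM at least 5, fewer genes were tested: 2583 were lower and 8 lists called in MIM-Astrocytes against Astrocytes, 4135 higher and 3610 lower in NSC against Astrocytes, 2558 lower in MIM-Astrocytes against NSC, 2304 and 2928 lower in Glioblastoma against NSC and Astrocytes, 5161 shared, and the Glioblastoma correlation was 0.71. Without a filter, where more genes were tested, 6427 and 8062 were lower in Glioblastoma against NSC and Astrocytes. Rescaled to a common total, 3120, 3468 and 4833 genes were higher in MIM-Astrocytes, NSC and Glioblastoma against Astrocytes and 2581 lower in MIM-Astrocytes against NSC, with a Glioblastoma correlation of 0.71. Without mitochondrial genes and small RNAs those higher than Astrocytes were 3804, 4142 and 5205. With protein-coding genes only, 4863 were higher in Glioblastoma against NSC and the correlations were 0.837 and 0.714. A pseudocount of 0.1 gave 0.68 for Glioblastoma.

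Signs changed for Trp53 in NSC against Astrocytes (-0.09 rescaled to a common total), Olig2 in Glioblastoma against NSC (-0.14 median-of-ratios, -0.3 quantile, -0.3 protein-coding), Mki67 there (-0.21 quantile, -0.21 protein-coding) and Nes in Glioblastoma against Astrocytes (-0.22 quantile, -0.43 rescaled, -0.4 without mitochondrial genes and small RNAs). A replicate block gave 5928 higher and 4526 lower in MIM-Astrocytes against Astrocytes, and 5342 and 4153 within the 6 libraries. Spread models and array weights were not run for any gene list. Of simulated changes, 26% at 0.25 and 86% at 1 were found, but with 200 genes changed, too few to give the real sensitivity.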

Other observations

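The genes here were chosen after their values were seen, and no explanation for them was tested. MIM-Astrocytes went beyond both Astrocytes and NSC for many genes: 2156 were higher than in both groups, 337 of them by at least 2-fold in each, and 1078 lower, 63 by at least 2-fold. The insulin-like growth factor binding protein genes Igfbp4 and Igfbp2 stood at 318 ± 26.7 and 968 ± 62.8 FPKM, against 45.4 ± 3.81 and 188 ± 18.3 in NSC and 7.07 ± 0.417 and 182 ± 19.4 in Astrocytes (mean ± SD, n = 3). Gpd1, glycerol-3-phosphate dehydrogenase, stood at 156 ± 16.4 against 23.2 ± 1.9 and 9.69 ± 1.05, and Pycr1, an enzyme of proline synthesis, at 7.3 ± 0.777 against 0.93 ± 0.205 and 0.46 ± 0.0639. In the other direction, Txnip was 6.77 ± 0.812 against 96.8 ± 9.36 and 83.8 ± 5.6, Tnc 1.81 ± 0.127 against 28.9 ± 1.27 and 41.3 ± 1.6, and Id3, a target of BMP signalling, 11.3 ± 0.712 against 36.7 ± 4.48 and 264 ± 31.9.

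Regional genes of the Glioblastoma cultures, labelled with cerebella, went apart. The midbrain and hindbrain genes En1 and En2 stood at 2.45 ± 0.0913 and 2.76 ± 0.167 FPKM against 0.276 ± 0.037 and 0.256 ± 0.0439 in NSC, and Irx2 and Hoxa3 at 6.57 ± 1.31 and 2.19 ± 0.302 against 1.45 ± 0.168 and 0.0124 ± 0.0116. Zic1, a gene of cerebellar granule cell precursors among other places, was at 0.0457 ± 0.0487 against 24.1 ± 2.3. The forebrain gene Lhx2 was at 5.67 ± 0.594 against 25.8 ± 0.872, and Emx2 at 4.82 ± 0.572 against 3.69 ± 0.297.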
